A study of Mus musculus with 2 samples.

How the data were processed

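H3K4me2 ChIP-seq was carried out on hindbrain from mouse embryos at 15.5 days of development, in 2 biological replicates, pools of 78 and 62 embryos of mixed sex, with fragments of 300 to 500 bp per the labels. Replicate numbers and the single group were taken from the labels. Each replicate is a separate pool of embryos, so differences between them include biological and technical variation together.

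The authors deposited 4 peak lists in narrowPeak format on mm10. Per the text files deposited with the samples, the list of replicate 1 came from its own alignments and a control, that of replicate 2 from its own alignments and another control, and the pooled list from both. The replicated list was derived from the other 3 lists. Each of its peaks is also in the pooled list. The aligner, the peak caller and their versions are not given in the sources used here, nor is the rule by which peaks entered the replicated list. Each peak carries the fold over control deposited by the authors, a linear ratio, and the deposited −log10 of its p-value and q-value. These are the peak's own values and served only to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each library is unknown and no counting interval is given. A peak list holds only regions past the authors' threshold, so a gene without a peak had no call rather than a measured level of 0, and a more deeply sequenced library could add weak peaks. How far a peak extends also depends on the caller, so widths were compared only between genes within the same lists.

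Coordinates are 1-based on mm10 (GRCm38). Gene models came from GENCODE release M21 and sequence from the RefSeq GRCm38 patch 6 assembly. All peaks on chromosomes lay inside the chromosome lengths of that assembly (0 past an end). The 21938 protein-coding genes on chromosomes 1 to 19, X and Y each had 1 TSS at the gene's 5′ end. Some gene models start far upstream of the main promoter, so values at any annotated start are given beside genes where this matters. Peaks on unplaced sequence were left out of gene comparisons.

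A promoter was the TSS ± 1 kb and was marked when a replicated peak overlapped it by at least 1 bp. Breadth was the number of bp within the TSS ± 5 kb (10001 bp) covered by peaks. Distal peaks lay more than 1 kb from every protein-coding TSS and were assigned to the nearest within 100 kb. Per gene, values are given from the replicated list, or as the mean ± SD of the values from each replicate's own list (n = 2). A replicate peak was shared when an overlap spanned at least 50% of either peak, and the overlap was set against 100 circular shifts within chromosomes. A CpG ratio, observed over expected, was computed over the promoter, and genes were split into 10 strata of it for matched random lists.

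Gene lists were Hox paralogs 1 to 5, 6 to 8 and 9 to 13, rhombic lip and granule lineage, cerebellar GABAergic and Purkinje lineage, brainstem neuron identity, forebrain transcription factors, pan-neuronal, neural progenitor, oligodendrocyte and astrocyte, endothelial, microglia and macrophage, mural and meningeal, erythroid, liver, gut and pancreas, muscle and heart, housekeeping, and olfactory and vomeronasal receptors. No gene was in more than 1 list (0 shared). Of the 15 erythroid genes 14 were found among protein-coding symbols, Ahsp being the other. Promoter marking was tested with Fisher's exact test (two-sided) against all other protein-coding genes. Breadth (median) and distal peaks (mean) were tested against 10000 random lists of the same size, whose smallest two-sided permutation p is 2e-04. Pairs of lists were compared by a two-sided permutation test of 100000 resamples, smallest p 2e-05, with Fisher's exact test for their promoters, and these 4 p-values were adjusted together. All adjustments used Benjamini-Hochberg, over the 18 lists for list tests, with a threshold of 0.05. Genes and peaks are not replicates, so these p-values describe the peak lists. No other splits of the samples could be tested with 1 group.

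Genes named in the text were, in each list, the 2 with the most covered bp and up to 2 without a replicated peak at the promoter (first by alphabet), the 10 genes with the widest domain over the TSS, and the genes nearest the 5 peaks of highest fold. Lists, windows, tests, this rule and the alternatives below were fixed before the data were examined. Other genes named, such as Barhl2, Sox2, Pax2, Hoxc11 and Hoxc12, were chosen after their values were seen.

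Alternatives covered the overlap rule, equal numbers of top peaks by p, a stricter threshold (−log10 q of at least 2), peaks merged within 500 bp, ranks by −log10 p, the pooled list, the upper 50% of replicated peaks by fold, each replicate's own list, promoter windows of 500 bp and 2.5 kb, any annotated start, a breadth window of 10 kb, a distal limit of 50 kb, autosomes only, and random lists matched on CpG ratio or on the distance to neighbouring start sites. Restricting to replicated peaks that overlap both replicates, and means in place of medians, were added after seeing the data.

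The functions were tested on simulated data. For the replicate overlap, a list that kept 75.03% of replicate 1's peaks with shifted edges was recovered at 75.42%. Coverage and distal assignment matched direct counts (0 differences). For the gene lists, tested on 21938 genes, random lists of 20 genes passed the unadjusted threshold in 1.0% of draws for promoter marking, 1.5% for breadth and 5.0% for distal peaks. Lists with 9 times the odds of broadly covered genes passed in 50.5%, 99.0% and 21.0%. With 3 times the odds they passed in 10%, 65% and 9%, so weaker differences could be missed. Lists with 9 times the odds of unmarked genes passed in 99.5% for marking and in 0% for median breadth. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.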

Results

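H3K4me2, a histone modification found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in hindbrain dissected from mouse embryos at 15.5 days of development. The series held 1 group with 2 biological replicates of mixed sex, a pool of 78 embryos and a pool of 62 embryos of the B6NCrl strain, so no contrast between conditions was possible. The hindbrain gives rise to the cerebellum, pons and medulla, and the comparisons asked which gene groups carried the mark and whether both pools gave the same regions. The authors deposited 48778 peaks for replicate 1 and 49201 for replicate 2, covering 57.7 Mb and 55.7 Mb of mm10. Their list called on both replicates together held 50890 peaks, and 38376 of these formed their replicated list, which covered 2.20% of the assembled chromosomes. Peaks carried no read counts, so the sequencing depth behind each list was unknown.

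In the Hox clusters, which pattern the body axis from head to tail, H3K4me2 was broad over the anterior paralogs and sparse over the posterior ones. The replicated list held a 52.1 kb domain at chromosome 11, 96295380 to 96347517, over the start sites of Hoxb3, Hoxb4 and Hoxb5, the widest domain in the genome. The next widest spanned 30.2 kb at chromosome 6, 52156236 to 52186416, and covered the start sites of Hoxa1, Hoxa2 and the neighbouring 5730596B20Rik. Within 5 kb of the transcription start site (TSS), the 15 genes of paralog groups 1 to 5 had a mean of 6538 bp covered (SD 3715 across genes), against 569 bp (SD 627) for the 16 genes of groups 9 to 13. The whole 10001 bp window was covered at Hoxa2 in both replicates and 9891 ± 72.1 bp at Hoxa5 (SD, n = 2 replicates), whereas Hoxa11 (chromosome 6, 52242106 to 52245810) had no peak there in either.

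The difference between these groups was 5968 bp, and it was 5853 bp in replicate 1 and 5779 bp in replicate 2. A two-sided permutation test across genes gave p = 2e-05, the smallest value its resamples allowed (adjusted p = 8e-05). All 4 clusters pointed the same way, with mean differences of 8372 bp in Hoxa, 6959 bp in Hoxb, 2501 bp in Hoxc and 1776 bp in Hoxd. The Hoxc and Hoxd values depend on the start used. Hoxd3 and Hoxd4, with 5′ ends at 74711927 and 74711929, had 2733 bp each there but 9919 and 8686 bp around other annotated starts. For Hoxc5 these were 426 and 7997 bp and for posterior Hoxc9 343 and 936 bp, while Hoxd1 stayed at 2095 bp. Promoters, taken as the TSS ± 1 kb, held a peak at 14 of 15 anterior and 8 of 16 posterior genes (Fisher's exact test, p = 0.0155, adjusted p = 0.0207). Hoxb9 had the broadest coverage of the posterior group, 2058 ± 550 bp (SD, n = 2 replicates), followed by Hoxd13 with 1278 ± 25.5 bp. Hoxa9 had no replicated peak within 1 kb of any annotated start. The 884 bp covered within 5 kb of one of them were the peak over the start of Hoxa7, at 52221204 to 52222087. The exception among the anterior genes was Hoxc4, which had no peak within 1 kb of its annotated 5′ end but 4776 ± 317 bp covered in the wider window, and 9206 bp around another of its annotated starts. The annotated 5′ end of Hoxc5 lies beside Hoxc10, and the promoter peak counted for both was called in replicate 1 only. Paralogs 6 to 8, the intermediate group, were all marked (8 of 8), with 8605 ± 25.5 bp at Hoxa6 and 8644 ± 232 bp at Hoxb7. In replicate 2's own list 7 were marked, the Hoxc8 promoter peak being called in replicate 1 only. Neighbouring Hox genes share domains and are not independent, so the p-values describe these peak lists.

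**Figure D1:**
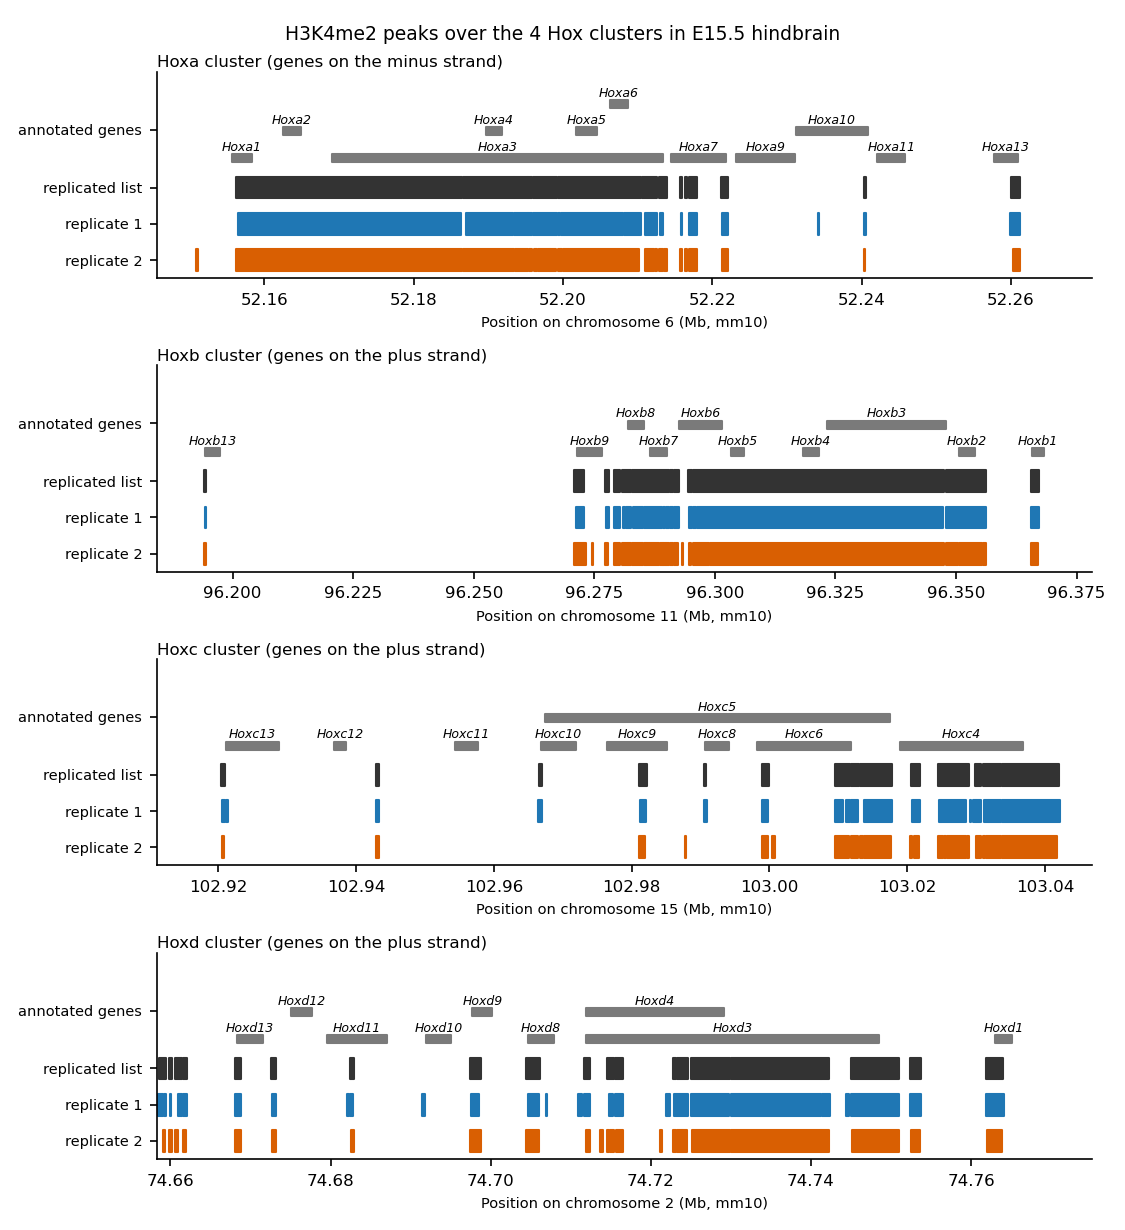
Replicated, replicate 1 and replicate 2 H3K4me2 peaks over the 4 Hox clusters, with position in Mb of mm10 on the horizontal axis, a bar per peak and grey bars for annotated genes. Near-continuous peaks lie over Hoxa1 to Hoxa6 and Hoxb2 to Hoxb5, while the posterior end of each cluster holds short isolated peaks, and Hoxa11, Hoxc11 and Hoxc12 have no covered base within 5 kb of their start sites.

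Neural gene lists carried broader H3K4me2 around their start sites than the genome at large, where the median protein-coding gene had 2079 bp covered. Neural progenitor genes reached a median of 6275 bp (5983 ± 75 bp, SD of the medians of n = 2 replicates), with 8410 ± 408 bp at Dll1, a Notch ligand, and 7095 ± 153 bp at Sox1. Rhombic lip and granule cell genes reached 6196 bp, with full coverage at the homeobox gene Meis2 (10001 bp in both replicates) and 9874 ± 180 bp at Zic1. The cerebellar GABAergic and Purkinje list reached 6171 bp, led by Lhx1 with 10001 bp and Slc32a1, the vesicular GABA transporter, with 9972 ± 40.3 bp. Pan-neuronal genes reached 5775 bp, with 8189 ± 24.0 bp at Celf4 and 7475 ± 212 bp at Myt1l. Brainstem neuron identity genes had a median of 4112 bp, with 9796 ± 291 bp at Lmx1b, required for serotonergic neurons, and 8380 ± 1317 bp at En1, a midbrain and hindbrain homeobox gene.

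Of the 18 lists tested, 8 were broader than random gene lists of the same size and 1 was narrower, at an adjusted permutation p under 0.05. For Hox 1 to 5 (7082 bp), rhombic lip, cerebellar, brainstem, pan-neuronal and progenitor genes the adjusted permutation p was 5.14e-04, reached at the smallest p that 10000 random lists allowed. Hox 6 to 8 (4768 bp) and housekeeping genes (3707 bp) also passed, each with an adjusted permutation p of 0.0036, with 6150 ± 122 bp at Polr2a, which encodes the large subunit of RNA polymerase II, and 5580 ± 19.1 bp at the ubiquitin gene Ubc. Olfactory and vomeronasal receptor genes, which act in sensory neurons of the nose, were the narrower list, with a median of 0 bp and the same adjusted permutation p of 5.14e-04. The medians did not pass for posterior Hox genes (427 bp, adjusted permutation p = 0.163), forebrain transcription factors (1876 bp, p = 0.786), oligodendrocyte and astrocyte genes (2195 bp, p = 0.809), endothelial genes (1821 bp, p = 0.786) or mural and meningeal genes (1875 bp, p = 0.786). Nor did they pass for microglia and macrophage genes (0 bp, adjusted permutation p = 0.170), erythroid genes (0 bp, p = 0.132), liver, gut and pancreas genes (0 bp, p = 0.129) or muscle and heart genes (330 bp, p = 0.132). Some of these medians moved with the peak list. In replicate 2 alone the endothelial median was 1062 bp, that of muscle and heart genes 110 bp and that of microglia genes 214 bp, and in the upper 50% of peaks by fold the posterior Hox, endothelial and muscle medians were 0 bp and the glial median 170 bp. A median of 0 can hardly fall below random lists of these sizes; with means in place of medians, a choice made after the data were seen, 14 lists passed, 8 broader and 6 narrower. The Hox 6 to 8 call ended in the upper 50% of peaks by fold (2950 bp, adjusted permutation p = 0.228), and the receptor call against CpG-matched lists (adjusted permutation p = 1). Against CpG-matched lists, posterior Hox genes (427 bp against 2932 bp, adjusted permutation p = 6e-04) and forebrain factors (1876 bp against 2787 bp, adjusted permutation p = 0.00154) were narrower. Around any annotated start, oligodendrocyte and astrocyte genes were broader (3557 bp, adjusted permutation p = 0.0198).

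Forebrain transcription factors differed from brainstem identity genes in breadth but not in promoter marking. Mean coverage was 2339 bp (SD 1656) over 24 forebrain factors and 4681 bp (SD 3112) over 29 brainstem genes, a difference of 2342 bp. A two-sided permutation test gave p = 0.00142 (adjusted p = 0.00284), and the difference was 2472 bp in replicate 1 and 2017 bp in replicate 2. Promoter marking stood at 21 of 24 and 25 of 29 (Fisher's exact test, p = 1). Bcl11b, also expressed outside the forebrain, had the broadest forebrain-list coverage with 8218 ± 84.9 bp (SD, n = 2), followed by Lhx2 with 3918 ± 501 bp. Fezf2, a cortical projection neuron factor, had 910.5 ± 204 bp and Nkx2-1, a ventral forebrain factor, 1388 ± 98.3 bp, both with no replicated peak within 1 kb of their 5′ ends but one at another annotated start.

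**Figure D2:**
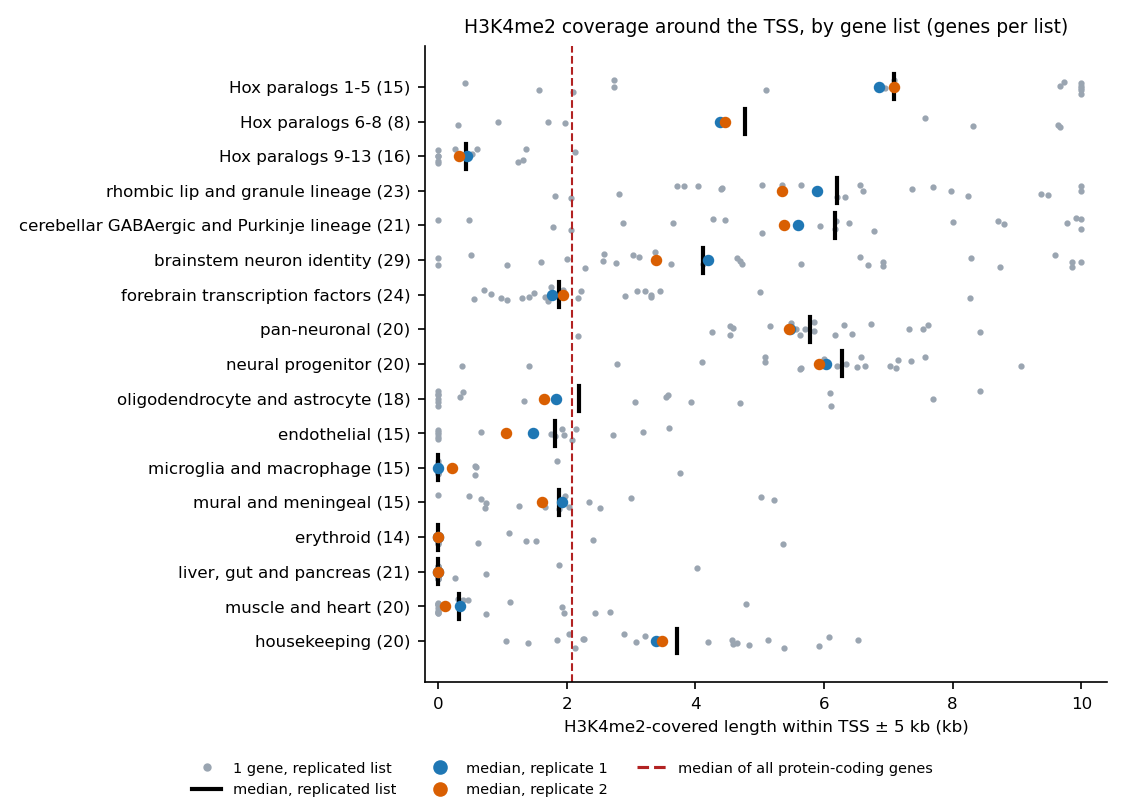
Length covered by H3K4me2 peaks within 5 kb of the TSS, in kb, for each gene of 17 fixed lists (grey points, replicated list) with the list median (black line) and the medians in replicate 1 and replicate 2 (coloured points). The dashed line marks the median of all protein-coding genes, 2079 bp; Hox 1 to 5, rhombic lip, cerebellar, pan-neuronal and progenitor medians lie between 5775 and 7082 bp, and the posterior Hox median at 427 bp.

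Peaks concentrated at promoters and avoided intergenic sequence. Of the replicated peaks on assembled chromosomes, 36.6% overlapped a protein-coding promoter, where 100 circular shifts of the list along each chromosome averaged 2.84% and reached at most 3.16%. Intergenic peaks made up 29.3%, against 58.3% in the shifted lists, and peaks in gene bodies outside promoters 34.1% against 38.9%. Promoter peaks were taken out of the gene body class first, so its lower share does not show that peaks avoided gene bodies. In the replicates' own lists the promoter share was 31.2 ± 1.10%, the intergenic share 28.9 ± 0.61% and the gene body share 39.9 ± 0.47% (SD, n = 2). The last was above the shifted mean rather than below it but within the range of the shifts (at most 40.4%). Only the replicated list was shifted, so the replicates' lists have no shifts of their own. Promoter share rose with the authors' fold over control, from 4.27% of the lowest quartile of replicated peaks to 79.8% of the highest, and was 67.1% in the upper 50% of peaks by fold. The strongest peak lay over the start of Adgrg6, a G protein-coupled receptor gene (chromosome 10, 14544086 to 14546524, fold 78.2). It was followed by peaks at Tysnd1 (fold 74.5), Acvr1c (72.6), 2156 bp from the 5′ end of Tbc1d1 (72.5) and at the immediate early gene Egr1 (71.8). Tbc1d1 had a peak within 1 kb of another annotated start. Coverage around another start reached 3608 bp, the width of the peak of high fold.

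The mark was present at the promoters of 14098 of 21938 protein-coding genes, or 64.3%. Replicate 1 alone gave 14167 promoters and replicate 2 gave 14120, with 14025 in common, 142 in replicate 1 only and 95 in replicate 2 only. All 20 pan-neuronal and all 20 progenitor genes were marked, as were 19 of 20 housekeeping genes, 22 of 23 rhombic lip genes, 25 of 29 brainstem genes and 14 of 15 anterior Hox genes. Marking was rare at genes of other organs and of microglia, macrophages and erythroid cells. It covered 2 of 21 liver, gut and pancreas genes, 6 of 20 muscle and heart genes, 1 of 15 microglia and macrophage genes, 4 of 14 erythroid genes and 3 of 1466 olfactory and vomeronasal receptor genes.

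By Fisher's exact test with Benjamini-Hochberg adjustment, 7 of 18 lists had more marked promoters than other genes and 5 had fewer. Adjusted p-values from Fisher's exact test for the higher lists were 7.56e-04 for pan-neuronal and progenitor genes, 0.00223 for rhombic lip, 0.00821 for housekeeping, 0.0209 for brainstem, 0.0257 for Hox 1 to 5 and 0.0267 for forebrain factors (21 of 24). For the lower lists, adjusted Fisher's exact test values were 2.63e-06 for liver, gut and pancreas, 3.30e-05 for microglia, 0.00528 for muscle and heart and 0.0184 for erythroid genes. The share of receptor genes lay below all 10000 random lists. Marking of the remaining lists did not pass Fisher's exact test after adjustment. By adjusted Fisher's exact test these were posterior Hox (8 of 16, p = 0.334), Hox 6 to 8 (p = 0.0736), cerebellar GABAergic and Purkinje (18 of 21, p = 0.0573), oligodendrocyte and astrocyte (10 of 18, p = 0.493), endothelial (10 of 15, p = 1) and mural and meningeal genes (13 of 15, p = 0.124).

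Marking followed promoter CpG content closely, from 0.593% of genes in the lowest CpG decile to 99.6% in the highest. Against random lists matched on CpG content, 5 lists passed in place of 12, namely pan-neuronal and mural and meningeal genes above and posterior Hox, liver, gut and pancreas, and receptor genes below. Posterior Hox genes were marked at 8 of 16 promoters where CpG-matched lists averaged 96.9% (adjusted permutation p = 0.0012), and mural and meningeal genes at 86.7% against 60.4% (adjusted permutation p = 0.0198). The remaining higher and lower calls ended there, and microglia genes had an adjusted permutation p of 0.327. Among other changes, the Hox 1 to 5 call ended in replicate 2's own list (86.7%), the forebrain call in replicate 1's own list (83.3%), and both when only peaks overlapping both replicates were kept (86.7% and 83.3%). Forebrain marking fell below that of other genes within 500 bp (62.5%). Calls also ended for brainstem genes within 500 bp (82.8%) and for muscle and heart genes within 2.5 kb (10 of 20). In the upper 50% of peaks by fold, the higher calls of brainstem genes (65.5%, adjusted p = 0.793 by Fisher's exact test), Hox 1 to 5 and forebrain factors (54.2%) ended, and posterior Hox genes were marked less often than other genes (12.5%, adjusted p = 3.71e-04 by Fisher's exact test). Cerebellar genes passed at any annotated start (95.2%) and mural and meningeal genes within 2.5 kb (93.3%).

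Individual genes within the lists varied. In the endothelial list Esam had 3383 ± 362 bp covered around its start and Kdr, a vascular growth factor receptor, 3246 ± 612 bp (SD, n = 2), while Emcn and Ly6c1 had none. Foxc1 and Pdgfrb led the mural and meningeal list with 4944 ± 87.0 bp and 4283 ± 112 bp, and Col3a1 and Lum had no promoter peak. Among microglial genes, Aif1 and C1qa had no promoter peak, and the 3662 ± 160 bp within 5 kb of Cd68 lay outside its promoter, as did the 1805 ± 218 bp near Spi1. The erythroid list was led by Tal1 (4143 ± 758 bp) and Epor (2240 ± 288 bp), with none at Alas2 or Gata1. Olig2 had 6640 ± 835 bp and Pdgfra 6596 ± 422 bp in the glial list, and the astrocyte genes Aldh1l1 and Aqp4 had no peak at their 5′ ends, though both had one at another annotated start. Apoh (3958 ± 26.2 bp) and Mylpf (4540 ± 239 bp) were the most covered of the liver and muscle lists, with no promoter peak at Ahsg or Acta1. Ahsg had no covered base within 5 kb, whereas Acta1 had 2390 ± 36.1 bp there. Apoa1 (1762 ± 24.7 bp) and Tnni3 (2462 ± 56.6 bp) came next in these lists with no replicated peak within 1 kb of the 5′ end.

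Several genes of the neural and housekeeping lists lacked a peak at the annotated 5′ end yet had one at another annotated start. They included Gad1, the GABA-synthesising enzyme gene (477 bp around its 5′ end and 10001 bp at another start), Zic3 (2069 and 7441 bp), Esrrb (0 and 4547 bp), Isl2 (2579 and 3969 bp) and Ywhaz (3073 and 6998 bp). Six3 of the forebrain list (819 and 2425 bp) and Sox10 of the glial list (3060 and 3826 bp) were others. The same held for Afp (0 and 419 bp) and Gata4 (0 and 773 bp) among the lists of other organs. Dbh, which makes noradrenaline, had no covered base within 5 kb of any annotated start. Vmn1r4 (2965 ± 272 bp) and Olfr94 (1812 ± 80.6 bp) were the most covered of the receptor genes, and Olfr1 and Olfr10 had no covered base.

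**Figure D3:**
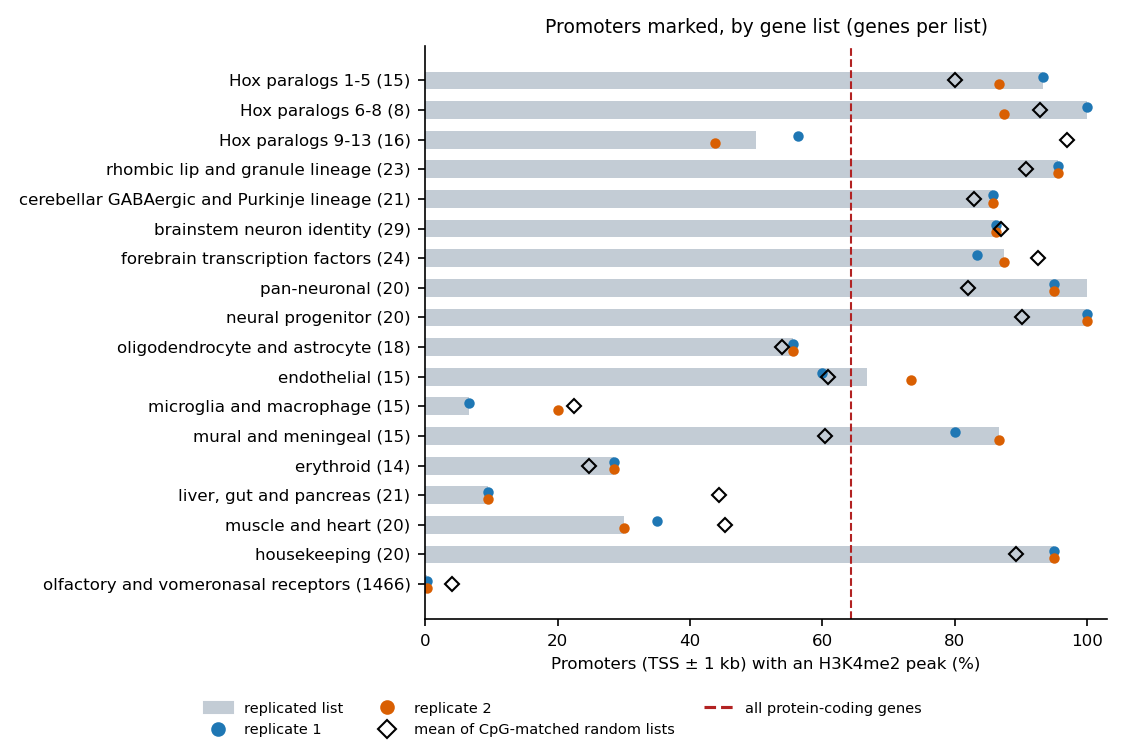
Share of promoters with an H3K4me2 peak, in %, for each of the 18 gene lists (bars, replicated list; points, replicate 1 and replicate 2), with the mean of CpG-matched random lists as open diamonds. The dashed line marks all protein-coding genes at 64.3%; posterior Hox genes stand at 8 of 16 where matched lists average 96.9%.

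Beyond the Hox clusters, the widest domains over protein-coding start sites included those at Meis2 and Pou3f3. Meis2 sat under 21.8 kb (chromosome 2, 116054987 to 116076803), Pou3f3 under 19.3 kb (chromosome 1, 42683497 to 42702815) and Mn1 under 18.3 kb (chromosome 5, 111414436 to 111432778). The start sites of Bcl11a and A830031A19Rik lay under the same domain of 17.7 kb (chromosome 11, 24073280 to 24090959). Coverage around these starts was 9930 ± 29.0 bp at Pou3f3, 8014 ± 166 bp at Mn1 and 6795 ± 124 bp at A830031A19Rik (SD, n = 2). The peaks of highest fold were narrower, 2439 bp wide at Adgrg6, 3053 bp at Tysnd1, 2201 bp at Acvr1c, 3608 bp near Tbc1d1 and 5359 bp at Egr1. Coverage within 5 kb of these starts was 2338 ± 4.95 bp at Adgrg6, 2932 ± 255 bp at Tysnd1, 2038 ± 121 bp at Acvr1c, 2732 ± 55.9 bp near Tbc1d1 and 5388 ± 433 bp at Egr1.

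Distal peaks, farther than 1 kb from the 5′ end of every protein-coding gene, numbered 24302, or 63.4% of those on chromosomes. Of these, 18397 lay within 100 kb of the nearest 5′ end. Peaks at other annotated starts of a gene count as distal here. With any annotated start, the promoter share of peaks rose from 36.6% to 45.2%. Progenitor genes had the most, a mean of 5.70 per gene, with 13 at Sox2 and 11 at Sox1. Rhombic lip genes averaged 4.65, cerebellar genes 4.19, brainstem genes 3.90, forebrain factors 3.88, oligodendrocyte and astrocyte genes 2.61 and pan-neuronal genes 2.60, where random lists averaged 0.837. Random lists matched on the distance to neighbouring start sites averaged more, from 0.961 for glial to 1.46 for cerebellar genes. All 7 lists passed against them too, with pan-neuronal genes the weakest (2.60 against 1.40, adjusted permutation p = 0.0382). Counts were higher in the replicates' own lists (means of n = 2 ± SD), with 7.85 ± 0.071 for progenitor, 7.33 ± 0.28 for rhombic lip, 6.10 ± 0.54 for cerebellar, 6.04 ± 0.049 for brainstem, 4.88 ± 0.12 for forebrain, 3.58 ± 0.35 for glial and 3.95 ± 0.071 for pan-neuronal genes. In the upper 50% of replicated peaks by fold they were lower, from 0.655 for brainstem to 1.65 for progenitor genes across these 7 lists, all of which passed again. Pax2, expressed in cerebellar inhibitory interneuron precursors, had 20 distal peaks, Lmx1b 14, Hoxc4 14 and Barhl2 11. Those of Hoxc4 include peaks within the gene itself, downstream of its annotated 5′ end.

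In all, 7 lists had more distal peaks than random lists and 1, the receptor genes with 0.0402 per gene, had fewer. Adjusted permutation p-values were 6e-04 for rhombic lip, cerebellar, brainstem, forebrain, progenitor and receptor genes, 0.00154 for pan-neuronal genes and 0.0018 for oligodendrocyte and astrocyte genes. Distal counts did not pass the permutation test for Hox 1 to 5 (1.80, adjusted p = 0.0720), Hox 6 to 8 (0.5, p = 0.688), posterior Hox (0.250, p = 0.121), endothelial (1.80, p = 0.0720) or mural and meningeal genes (1.53, p = 0.147). The same held for microglia (0.6, adjusted permutation p = 0.688), erythroid (0.571, p = 0.687), liver, gut and pancreas (0.333, p = 0.127), muscle and heart (1.05, p = 0.611) and housekeeping genes (1.5, p = 0.127). Hox 1 to 5 genes passed in replicate 2's own list (2.73, adjusted permutation p = 0.0396) and against lists matched on gene spacing (adjusted permutation p = 5.14e-04), as did housekeeping genes against spacing-matched lists (1.5 against 0.591, adjusted permutation p = 0.0128) and in the upper 50% by fold (p = 0.0231). In replicate 1's own list, endothelial genes had more (2.80, adjusted permutation p = 0.0324) and liver, gut and pancreas genes fewer (0.381, p = 0.0428). Hox 1 to 5 and endothelial genes also passed within 50 kb (1.53 each, adjusted permutation p = 0.0461), and endothelial genes with peaks overlapping both replicates (p = 0.0352). Of the 15 Hox 1 to 5 genes 7 had a distal peak, and Hoxc4 alone had 14, so these Hox calls lean on 1 gene. The nearest start need not be the gene a distal peak acts on.

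Both pools gave largely the same regions, and the shared peaks were the strong ones. Of replicate 1's peaks 76.7% overlapped a replicate 2 peak over at least 50% of either, and 79.9% of replicate 2's peaks did so in return. The mean of these 2 directions of a single comparison was 78.3%. Circular shifts gave at most 3.42% and 3.47%. The base-pair Jaccard index was 0.791, against at most 0.0129 in shifted lists, and Spearman's rho of fold across 35785 matched peaks was 0.919, across peaks, which are not independent replicates. Sharing rose from 35.4% and 43.4% in the lowest fold quartile of replicates 1 and 2 to 100% in the highest. The 11372 and 9885 unshared peaks were short, with median widths of 259 and 239 bp, and 4.09% and 4.26% of them lay at promoters, against 38.4% and 38.9% of shared peaks.

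**Figure D4:**
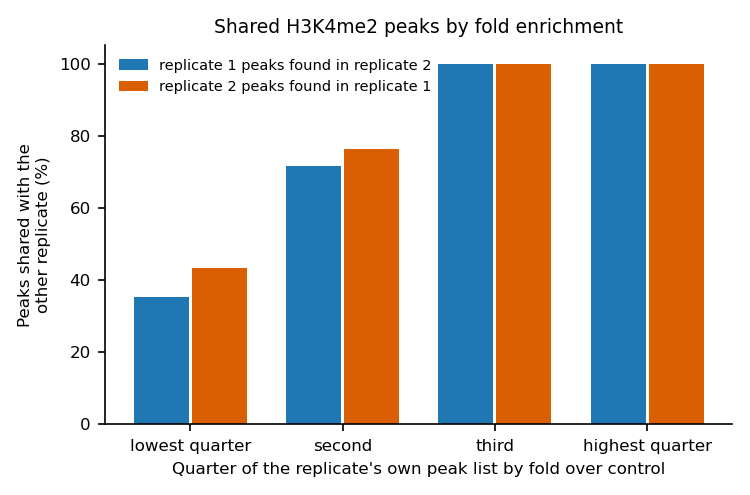
Share of each replicate's H3K4me2 peaks found in the other replicate, in %, by quartile of the replicate's own list ranked by the authors' fold over control (bars, replicate 1 and replicate 2). Sharing rises from 35.4% and 43.4% in the lowest quartile to 100% in the highest.

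Replication kept the strong pooled peaks. The replicated list retained 75.4% of the pooled peaks, from 8.17% of the lowest decile by fold to 98.5% of the fifth decile and 100% of each decile above it. Retained peaks had a median width of 1044 bp and a median fold of 11.3, against 253 bp and 2.63 for the 12514 left out, of which 3.71% lay at promoters. All 35705 pooled peaks that overlapped a peak of both replicates were retained, as were 2629 of 11277 that overlapped a peak of 1 replicate and 42 of 3908 that overlapped neither.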

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

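Tests chosen only after the result was seen were the one on transcription factors as a class, the one on the endothelial promoters alone and the count of vascular and meningeal lists above their CpG-based expectation. Signal was present in sequence that no gene comparison used. On scaffolds outside the assembled chromosomes, 20 replicated peaks lay on 6 scaffolds, with a highest fold of 20.8, and the replicates' own lists held 21 and 24 such peaks. No biological explanation was tested for it, since the design holds 1 group.

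Neural and hindbrain gene lists, and the housekeeping list, had broader H3K4me2 around their start sites than other genes. The CpG ratio within 1 kb of the TSS as the whole account was argued against. All 8 broader lists passed again against random lists matched on it, with housekeeping the weakest (adjusted permutation p = 0.0443). CpG content in the rest of the 5 kb window was not matched, so the test cannot decide on how far CpG-rich sequence extends. Breadth shared by all transcription factor genes was argued against by the forebrain factors. Their coverage was lower than that of brainstem genes (permutation p = 0.00142), and lay below CpG-matched lists (median 1876 bp against 2787 bp, adjusted permutation p = 0.00154). Breadth in part of the class stays open. Of the families chosen after the data were seen, Sox, Irx, Fox, Zfp and Lhx genes were broader than random lists (adjusted permutation p from 5.71e-04 to 0.0265). Those random lists were not matched on CpG content and included unmarked genes. The Zfp median (2345 bp) lay below the median of all marked genes, 2883 bp, and the Fox median (2926 bp) close to it. Pax genes did not pass (adjusted permutation p = 0.171). The authors' peak calling, transcription and the share of cells that use each gene were not tested and stay open.

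Unshared peaks numbered 11372 in replicate 1 and 9885 in replicate 2. Peaks near the calling threshold are a candidate explanation, as 99.75% of replicate 1's and 99.89% of replicate 2's unshared peaks lay in the lower 50% of their own list by fold. For a different cell makeup of the embryo pools, the largest difference between replicates in marked promoters of any marker list was 2, in the microglia list (1 against 3, the added genes being Laptm5 and C1qb) and in the endothelial list (9 against 11, Tek and Robo4), both higher in replicate 2. The rule set in advance counted differences up to 2 as evidence against it, but with 1 promoter to spare it was left undecided, a choice made after the value was seen. Depth differences between the libraries were not tested, since depth is unknown.

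A peak lay at 10 of 15 endothelial and 13 of 15 mural and meningeal promoters, shares that did not pass against other genes, and at 1 of 15 microglia and 4 of 14 erythroid promoters. CpG content as an account of both vascular lists was argued against by the mural and meningeal genes (13 of 15 against 60.4% expected, permutation p = 0.0044), but the endothelial list alone lay close to its CpG-based expectation (66.7% against 60.8%, permutation p = 0.774), as did erythroid genes (28.6% against 24.7%), and endothelial marking was 53.3% within 500 bp and 33.3% in the upper 50% of peaks by fold. Chromatin from vascular and meningeal cells in the dissected tissue stays open, since 1 of both lists, the mural and meningeal one, was marked more often than its CpG content predicts. In the mural list, Col1a1 had 1772 bp, Col1a2 1589 bp and Acta2 242.5 bp covered as replicate means. Use of these genes by neural cells stays open, as expression was not analysed here.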

How the results depend on the processing

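Only restricting to replicated peaks overlapping both replicates and means in place of medians were chosen after seeing the data. The cause of each shift below was not tested. Shared peaks of replicates 1 and 2 came to 79.9% and 83.3% with any overlap, 66.5% and 65.9% with 50% of both peaks, 79.0% and 83.1% at −log10 q of at least 2 (Jaccard index 0.802) and 80.9% and 83.6% with peaks merged within 500 bp (0.805). Rho by −log10 p was 0.957. The retained share of pooled peaks was 79.0% at −log10 q of at least 2. As a different measure, 82.7% of the pooled peaks overlapped a peak of replicate 1's own list and 79.8% one of replicate 2's, over at least 50% of either peak. Promoter share was 28.5% in the pooled list, 67.1% in the upper 50% by fold, 39.1% for peaks overlapping both replicates, 35.5% within 500 bp, 41.2% within 2.5 kb and 45.2% at any annotated start, with 30.4% to 32.0% when leaving out 1 replicate.

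Matching on CpG left 5 lists with promoter marking past the threshold, 3 of them among the original 12, and means in place of medians gave 14 lists for breadth. Among list calls that had passed the threshold, the direction turned in 6 cases. Promoter marking in the upper 50% by fold was 60% for Hox 1 to 5 and 54.2% for forebrain factors, which also fell below other genes within 500 bp (62.5%). In these 2 settings 13300 and 13889 of all 21938 genes were marked, so some of these values lay close to the share of other genes. Against CpG-matched lists it was 87.5% for forebrain factors (92.5% expected), 86.2% for brainstem genes (87.0%) and 28.6% for erythroid genes (24.7%), each on the other side of the expected share. Across single lists, 15 further values lost the threshold and 22 gained it in the same direction. Both pair comparisons kept their direction and threshold under every alternative run, with Hox differences from 5365 bp to 10790 bp and brainstem minus forebrain from 2017 bp to 3414 bp. Without replicate 1, Hox 1 to 5 lost its promoter call (86.7%, adjusted p = 0.133 by Fisher's exact test), and without replicate 2 forebrain factors did (83.3%, adjusted p = 0.0791 by Fisher's exact test). No paired analysis was possible because there is 1 group. Unknown depth limits any statement on weak peaks.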

Other observations

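Gene families were chosen by symbol after the data were seen, 20 in all, and tested as the lists were, with adjustment over the families. The families were not matched on CpG content or gene spacing. Some hold genes of the fixed lists, so each was also tested without them. Iroquois homeobox genes, which pattern the neural tube, had the broadest marking, with a median of 7883 bp within 5 kb of the TSS over 6 genes and 9799 ± 17.0 bp (SD, n = 2) at Irx2. Sox genes followed with 5773 bp, or 3928 bp (adjusted permutation p = 0.016) over the 11 outside the fixed lists, and ionotropic glutamate receptor genes with 5509 bp, led by Grik3 with 8758 ± 44.5 bp. Potassium channel genes had 3283 bp over 81 genes, with 8708 ± 260 bp at Kcnc3, ribosomal protein genes 3232 bp over 72 and replication-dependent histone genes 4536 bp over 67. All 6 families had an adjusted permutation p of 5.71e-04, and the 5 other than Sox had 8e-04 without genes of the fixed lists. Fox (2926 bp, adjusted permutation p = 0.0167), Lhx (3922 bp, p = 0.0265) and Zfp zinc finger genes (2345 bp, p = 0.0253) also passed, Lhx only with its list members. The median over all marked genes was 2883 bp, above that of Zfp genes and close to that of Fox genes. Clustered protocadherin, keratin, beta-defensin, bitter taste receptor and cytochrome P450 genes were narrower, with medians of 0 bp (adjusted permutation p of 0.0317 or less). Pax, Wnt, Fgf, collagen, GABA-A receptor (3178 bp, adjusted permutation p = 0.101) and serotonin receptor genes (2250 bp, p = 0.762) did not pass.

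Distal peaks were most frequent at Pax genes, with a mean of 7.33 per gene over 9 genes although only 5 of the 9 promoters were marked, and next at Lhx genes with 5 (adjusted permutation p = 5.71e-04 for both). The 7 Pax genes outside the fixed lists averaged 5.29 (adjusted permutation p = 8e-04), whereas 6 of the 8 Lhx genes were list members and the remaining pair did not pass (adjusted permutation p = 0.0723). Histone genes were the reverse, broad at the TSS with 0.358 distal peaks per gene (adjusted permutation p = 0.004). Neighbouring histone genes can share the same covered bases. Hist1h2ao and Hist1h2bq, with starts at 21810465 and 21810197 on chromosome 13, each had 607 bp covered. Close spacing also leaves less sequence that counts as distal. Whether spacing accounts for both values was not tested. Clustered protocadherin genes, which give neurons distinct surface identities, were marked at 19 of 57 promoters (Fisher's exact test, adjusted p = 6.98e-06), with 7924 ± 590 bp at Pcdhgc5 and 5738 ± 68.6 bp at Pcdhgc3, of the C-type isoforms. Beta-defensin and bitter taste receptor genes had 0 of 42 and 0 of 35 promoters marked, and cytochrome P450 genes 22 of 99.

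The genes of the neuronal microRNA miR-9 lay under wide domains. Mir9-1 (chromosome 3, 88215598 to 88215686) sat in the peak of width rank 3 among all replicated peaks, 23.1 kb long, and Mir9-3 (chromosome 7, 79505264 to 79505353) in that of rank 12, 17.4 kb. Mir9-2 (chromosome 13, 83738814 to 83738885) sat in an 8.28 kb peak of rank 154, separated by 115 bp from a 21.7 kb peak over the start of C130071C03Rik. Of 2199 other annotated microRNA genes, 285 lay under a peak and 12 under one at least as wide as that of Mir9-2, including Mir10a, Mir124a-3 and Mir125b-1. Wide domains with no protein-coding start also lay inside Nfib (22.3 kb, chromosome 4, 82492367 to 82514705) and inside Zfhx3 (18.3 kb, chromosome 8, 108701032 to 108719362).

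Forebrain factors had many distal peaks, while their breadth at the TSS did not pass against random lists (adjusted permutation p = 0.786) and was lower than that of CpG-matched lists and of the brainstem list. At least 1 distal peak was assigned to 22 of the 24, with 10 at Lhx2 and 10 at Bcl11b. CpG-rich promoters without any mark were rare, at 23 of 4387 genes in the top 2 CpG deciles with no peak in the replicated list or either replicate, among them Hoxa11 and Cdx2, a gene of the gut and posterior body. Long intergenic RNA genes more than 1 kb from a protein-coding start were marked at 15.9% of 5513, antisense genes at 26.2% of 2327 and processed pseudogenes at 2.90% of 9897. Rbfox3, a neuronal splicing factor gene, had a promoter peak in the replicated list (fold 32.9) but in neither replicate's own list. Both replicates nevertheless had peaks nearby, covering 4099 and 4201 bp within 5 kb of its start, against 4262 bp in the replicated list. Peaks that entered the replicated list without overlapping both replicates numbered 2671, with a median width of 382 bp and a median fold of 3.20.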
